A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

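DNase-seq libraries came from 1 WT culture and 1 culture of the Hsp90 G170D strain, both W303, and samples were grouped by their source labels. Per the labels' protocols, nuclei were digested lightly with DNase I, fragments were size-selected (described there as short, with the sign >650 bp), and libraries were sequenced for 101 cycles on a HiSeq2000. The submitters' processing notes name FastQC 0.10.1, Bowtie 1.0.0 and the sacCer3 build, with no order or settings. The hotspot caller, its threshold and any read filter are not given in the sources used here. Each deposited file lists hotspots as chromosome, start, end and a score, called per sample. What the authors' score measures is not given in the sources used here, so it was used only to rank hotspots within their own list. The lowest deposited score was 3.30 in WT and 3.43 in G170D. Since the number and width of called hotspots move with depth and digestion, the number, covered length and mean width of each list are given together. Depth is unknown, and score values were not compared between lists.

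Coordinates were set against RefSeq gene coordinates of assembly R64, which is sacCer3, for 6002 protein-coding genes on 16 chromosomes, 5257 of them with a standard symbol. Strand was read from the letter W or C of the systematic gene name, and 0 coding genes lacked it. As a check of build and strand, 64.4% of coding genes had a WT hotspot at the base 100 bp upstream of the start and 40.6% at 100 bp downstream of it. Coordinates are printed counting from 1. The annotation gives coding bodies without untranslated regions, and chromosome lengths were taken as the last annotated or called base.

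Hotspots were called shared when they overlapped by at least 1 bp. Shared shares were set against 1000 random placements of the G170D hotspots that kept chromosome and width. Shares of hotspots have 95% Wilson intervals, which cover counting error only. Widths were compared over hotspots that overlapped one to one. A promoter was the 500 bp upstream of the coding start. For 23 gene lists, the share of promoters kept, and the share gained in G170D, was given as a percentile among 10000 random lists of the same size, drawn for the kept share from the same of 5 classes of WT score. A list was called apart from random lists when it stood in their outer 2.5% on either side. Tied random lists counted only in part, so a list that kept every promoter or gained none could be held inside these limits. With 1 library per strain, percentiles describe these libraries and no p-value between strains was made. The 23 gene lists, the comparisons in the report and the alternatives not named as added later were fixed before the data were examined; the closing observations rest on measures chosen later.

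Named genes followed a fixed rule. For promoters with a hotspot in 1 strain, they were the 12 genes with standard symbols and the highest scores per direction, with divergent partners. For shared upstream hotspots, they were the 5 largest losses and the 5 largest gains of width. From each list, up to 4 members were named alphabetically, those in 1 strain first, and HSP82, HSC82 and STH1 were always named. An item that this rule selects is not reported here. Where a promoter held several hotspots, the one with the highest score was described.

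Alternatives covered the score threshold, equal list lengths, merging of neighbours, chromosome ends and rDNA, the overlap rule, random placement, the promoter window, hotspot assignment and the matching of random lists. The code was tested on simulated lists of 7050 hotspots and on 6002 genes: 100% of sharing calls were right, a simulated width change of -50 bp was recovered as -50 bp, and 2 of 40 random lists fell in the outer 2.5% on either side. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A planned search for 23 sequence motifs was not run, because no genome sequence was used here.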

Results

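Hsp90 is an abundant chaperone that folds and stabilises kinases, receptors and transcription factors, and budding yeast encodes it in the paired genes HSP82 and HSC82. DNase-seq finds accessible chromatin as stretches of DNA that DNase I cuts readily in nuclei, and a caller reports such stretches as hotspots. The study asked which parts of yeast chromatin change when Hsp90 is inactivated, by comparing wild-type (WT) cells with cells that carry the temperature-sensitive Hsp90 allele G170D. Both strains were in the W303 background, a common laboratory strain. Cultures grew in rich medium at 30 °C from an optical density of 0.25 to 0.65 and were then moved to 37 °C medium for 15 min, which is not permissive for the mutant. Each strain gave 1 library and 1 deposited hotspot list, so every difference between strains is a difference between 2 libraries, with no replicate check and no test between conditions. Read numbers were not given in the sources used here, and the depth behind each list is therefore unknown. Both libraries followed the shift, and there was no library from before it for either strain. A difference already present at 30 °C thus cannot be told from one that arose when Hsp90 was inactivated. Words such as kept, gained and lost compare G170D with WT only.

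The WT list held 7050 hotspots and the G170D list 5988. WT hotspots covered 3.83 Mb, which is 31.8% of the 12.1 Mb between the chromosome starts and the last annotated or called bases, and had a mean width of 543 bp. G170D hotspots covered 3.33 Mb (27.6%) with a mean width of 556 bp. The median width was 329 bp in WT (quartiles 196 and 732 bp) and 326 bp in G170D (189 and 726 bp), while hotspots over 3000 bp numbered 28 in WT and 50 in G170D. Neither list held a mitochondrial hotspot.

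At HSP82 itself (chromosome XVI, 96496 to 98625, sacCer3, minus strand) the whole coding body and the whole 500 bp upstream of its start were covered in both strains. The WT hotspot there spanned 94480 to 99688 (5209 bp) and the G170D hotspot 95386 to 99535 (4150 bp). HSC82 (chromosome XIII, 632355 to 634472), the constitutively expressed Hsp90 gene, had a 371 bp hotspot in WT and a 283 bp hotspot in G170D, both upstream of the coding start. STH1 (chromosome IX, 117992 to 122071), which encodes the ATPase of the RSC nucleosome remodeller, had hotspots of 833 and 663 bp that covered its full upstream window. A hotspot list carries no sequence, so the allele itself was not checked. The labels do not say whether either strain carries extra copies of HSP82, which would add reads there.

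Most accessible regions of the mutant were also accessible in WT, and the WT list held more hotspots of its own, less so when both lists were cut to the same length. Of the 7050 WT hotspots, 5174 overlapped a G170D hotspot by at least 1 bp (73.4%, 95% Wilson interval 72.3 to 74.4), and 1876 were found in WT alone. Of the 5988 G170D hotspots, 5403 overlapped a WT hotspot (90.2%, 89.5 to 91.0), and 585 were found in G170D alone. Hotspots found in 1 strain were narrow, with a median of 167 bp for WT and 138 bp for G170D, and together covered 360 kb and 129 kb. When G170D hotspots were placed at random within their chromosomes 1000 times, 47.4% of WT hotspots were overlapped on average (range 46.0 to 49.1) and 54.1% of G170D hotspots overlapped WT (52.4 to 55.9). In bases, 2.73 Mb were common to both lists, equal to 71.1% of the WT length, 81.9% of the G170D length and 61.5% of their union. The intervals cover counting error over hotspots only, and asking for an overlap of at least 50% of both hotspots lowered the shared part to 49.3% of WT and 58.1% of G170D hotspots. With the 5988 highest-scoring hotspots of each list, 80.5% of WT and 85.8% of G170D hotspots were shared, which left 1165 in WT alone and 852 in G170D alone.

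Sharing rose with the authors' score, which ranks hotspots within a list and was divided into 10 classes of equal size, but random placement gave a rise as well. The median WT width went from 110 bp in class 1 to 1227 bp in class 10 (111 and 1463 bp in G170D), and wide hotspots overlap more often by chance. Only 31.8% of WT hotspots in the lowest class overlapped G170D, no more than after random placement (mean 33.6%, range 27.8 to 39.9 over 1000). The share was 77.7% in class 5 (random 43.7%) and 100% in the highest-scoring classes, 9 and 10 (random 61.4% and 69.2%). In the G170D list the lowest class already shared 70.9% (random 39.3%), and from class 5 upward the share stayed between 95.3% and 97.0%, against 78.6% by random placement in class 10. Among the 1410 WT hotspots in the top 20% of scores, 0 were found in WT alone. Among the 1198 G170D hotspots in the top 20%, 46 were found in G170D alone.

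**Figure D1:**
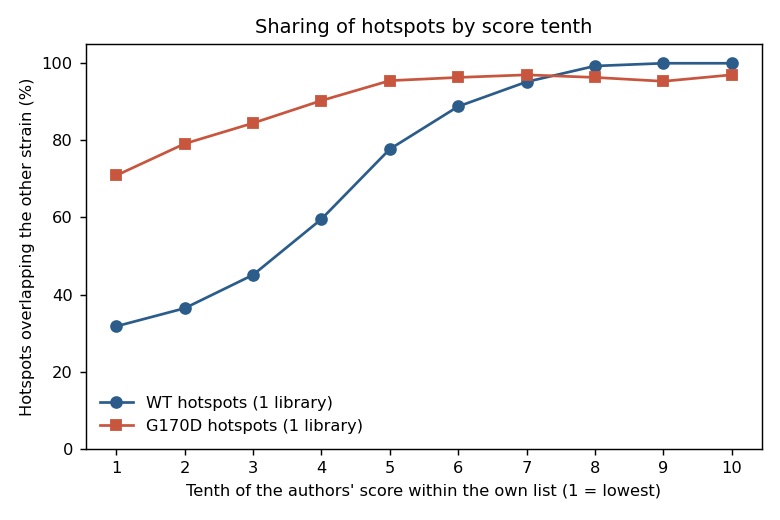
Share of hotspots that overlap a hotspot of the other strain (y axis, percent) by class of the authors' score within the own list (x axis, 1 lowest to 10 highest), 1 library per strain. WT sharing climbs from 31.8% in class 1 to 100% in class 10, while G170D sharing starts at 70.9% and ends at 97.0%.

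Where a region was accessible in both strains, it was usually a little narrower in the mutant. Over 3992 hotspots that overlapped one to one, the median width was 454 bp in WT and 338 bp in G170D. The median of the paired G170D minus WT differences was -50 bp (95% order-statistic interval -55 to -47), or -0.18 on the log2 scale. G170D was narrower at 2899 of them (72.6%), wider at 1074 and equal at 19. Narrowing prevailed in each of 5 classes of mean width, from 67.0% of hotspots in the widest class to 75.2% in class 3. Hotspots are not replicates, so the interval describes these 2 lists only.

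Large changes of width went both ways and took in neighbouring genes. Among upstream hotspots that overlapped one to one, the largest losses were at EMC10 and YOS9 (chromosome IV, 564827 to 566447 in WT), where 1621 bp in WT compared with 325 bp in G170D. At CDC10, a septin gene, and MRPL32 (chromosome III, 118077 to 119717) the hotspot was 1641 bp in WT and 502 bp in G170D. The hotspot of CPR5, a prolyl isomerase gene, and HNT2 (chromosome IV, 1072816 to 1074099) was 1284 bp in WT and 282 bp in G170D. SEI1 (1998 and 1041 bp) and SPS2 (1246 and 313 bp) completed the 5 largest losses. The largest gain was at OYE3, an NADPH oxidoreductase gene, and DAP1 (chromosome XVI, 226187 to 229713 in G170D), where 1280 bp in WT compared with 3527 bp in G170D. At XBP1, which encodes a stress-induced repressor, and SGA1 (chromosome IX, 176519 to 179432 in G170D) the hotspot went from 740 to 2914 bp and covered 1429 bp of SGA1. The regions of IXR1 (1050 and 3216 bp), ILV3 with ESS1 (1004 and 3122 bp) and RFX1 (840 and 2900 bp) followed.

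**Figure D2:**
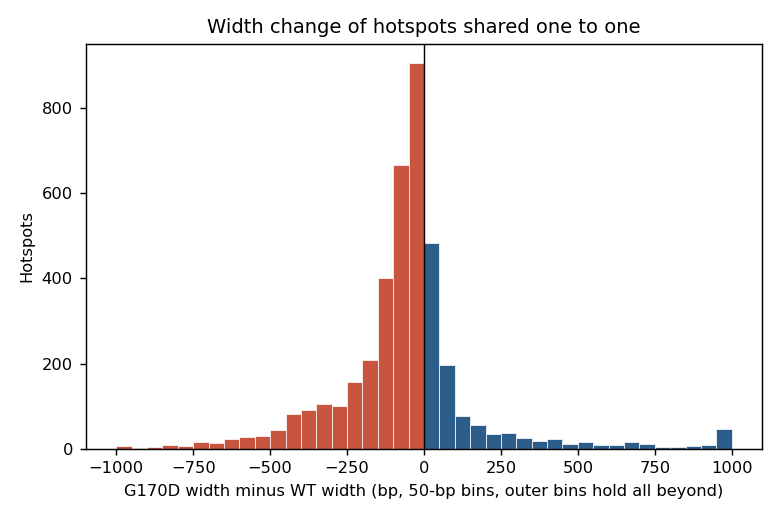
Number of hotspots (y axis) by G170D width minus WT width (x axis, bp, bins of 50 bp) for the 3992 hotspots shared one to one; the outermost bins hold all larger changes and the first bin right of 0 includes the 19 equal ones. Bars left of 0 (narrower in G170D) hold 2899 hotspots and bars right of 0 hold 1074 wider ones.

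Hotspots of both strains lay upstream of coding genes more often than randomly placed ones. The midpoint fell within 500 bp upstream of a coding start for 36.8% of WT hotspots (Wilson 35.7 to 38.0; mean of 100 random placements 21.3%) and for 38.8% of G170D hotspots (37.6 to 40.1; 21.2%). Coding bodies held 49.4% of WT midpoints and 44.9% of G170D midpoints, below the random 67.7% and 67.8%. Hotspots found in 1 strain lay upstream of a coding start about as often as randomly placed ones, at 20.6% for WT-only and 20.2% for G170D-only midpoints, against 42.7% and 40.8% of the shared WT and G170D hotspots. In coding bodies they made up 71.4% and 67.5%, against 41.4% and 42.4% of the shared ones.

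Genes of non-coding RNAs were counted without a test, beside 7050 WT and 5988 G170D hotspots in all. Of 76 genes for small nucleolar RNAs, which guide rRNA modification, 59 overlapped a WT hotspot and 45 a G170D hotspot, with 15 in WT alone and 1 in G170D alone. Transfer RNA genes were even, with 165 of 275 overlapped in WT and 163 in G170D, of which 22 and 20 were found in 1 strain. Among 21 other annotated non-coding RNA genes the same 15 were overlapped in both strains.

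Gene by gene, most promoters kept a hotspot in the mutant. A promoter was taken as the 500 bp upstream of the annotated coding start, for each of 6002 protein-coding genes. A hotspot overlapped it in both strains for 4344 genes, in WT alone for 575, in G170D alone for 219 and in neither for 864. Of the 4919 promoters with a WT hotspot, 88.3% (Wilson 87.4 to 89.2) had one in G170D too. Independent sets of the same sizes would share 3740 promoters, against the observed 4344. In promoters with a hotspot in both strains the median covered length was 437 bp in WT and 390 bp in G170D, with 2077 less covered in G170D, 1027 more and 1240 equal. The 1-strain classes depend on how a hotspot is assigned: with only midpoints counted, 2184 promoters were in both, 997 in WT alone and 677 in G170D alone. Requiring that the highest-scoring G170D hotspot of the window overlap no WT hotspot anywhere left 142 of the 219. Keeping only the higher-scoring 50% of each list gave 371. For 120 promoters in WT alone and 77 in G170D alone, the highest-scoring hotspot overlapped one of the other strain outside the window. Among list members named below, these include DIM1, RPL35B, RPA135 and PAU2 in WT alone. In G170D alone they include TAH1, HIS3, TRP5, PUP2, ERG1 and FIT2. Several list members named below as in WT alone rested on hotspots near the lowest WT score of 3.30. Scores were 3.37 at FUS2, 3.52 at ARN2, 3.57 at RNR1, 3.64 at PHO5 and NOP2, 3.68 at PRE8 and 3.74 at ARP7. The WT median was 7.27, and others scored higher, such as CDC37 (5.81), AHA1 (6.22) and FUS1 (7.73).

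The highest-scoring promoters found in 1 strain belonged to genes of varied function, and in all 24 cases the hotspot overlapped one of the other strain outside the promoter window. In WT alone these were PUS6, a pseudouridine synthase gene (hotspot on chromosome VII, 836380 to 837746), RPC31, an RNA polymerase III subunit gene (chromosome XIV, 348968 to 352301), and MET14, a sulfate assimilation gene (chromosome XI, 439858 to 441055). NMA1, SUT2, MCO6, JIP5, NUP42, CCE1, QCR9, CIT2 and HEM12 made up the rest of the 12. In G170D alone the highest score was at GTO3, a glutathione transferase gene, whose hotspot (chromosome XIII, 772851 to 775675) covered its full coding body and 64 bp of its promoter window. RRN5, which encodes an RNA polymerase I initiation factor, had a hotspot of 1818 bp (chromosome XII, 423425 to 425242) that also held its coding body. CDC24, the gene of the exchange factor for Cdc42, had 371 bp of its window covered (chromosome I, 60743 to 62710). RRT12 (chromosome III, 208135 to 209610) lay inside the widest G170D hotspot, 7246 bp from 207988 to 215233. GYP6, GTA1, OSW2, GID7, PET122, THI2, FRS2 and TAH1 completed the 12, TAH1 sharing its hotspot with the divergent gene YIH1.

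Nearly all chaperone and stress promoters kept their hotspots in the mutant. Of 28 genes controlled by Hsf1, the heat shock factor, 26 had a hotspot in both strains, and AHA1 in WT alone. The kept share of 96.3% stood at percentile 55.0 of 10000 random lists matched on WT score, whose mean was 95.4%. BTN2 (chromosome VII, hotspot 771336 to 773153 in WT) had hotspots of 1818 bp in WT and 1027 bp in G170D, and CPR6 (chromosome XII) of 1064 and 1557 bp. All 25 general stress genes of Msn2 and Msn4, the stress-responsive activators, that had a WT promoter hotspot kept it. Matched random lists kept 90.4%, which put the list at percentile 97.2. With all 25 kept this was the highest percentile open to it, so it could not reach the outer 2.5% with this matching. That percentile ranged from 87.3 with a 250 bp window to 97.85 without score matching. CTT1, the cytosolic catalase gene (chromosome VII, hotspot 652949 to 655354 in WT), had 2406 and 2383 bp, and CYC7 (chromosome V) 673 bp in WT and 3057 bp in G170D. Of 14 genes for Hsp90 and its cochaperones, 11 were in both strains, a kept share of 84.6% against 86.9% in matched random lists (percentile 38.3). AHA1, the ATPase activator of Hsp90 (chromosome IV, 892875 to 893927), and CDC37, the kinase cochaperone (chromosome IV, 790328 to 791848), were in WT alone with 500 and 242 bp of promoter covered, and TAH1 (chromosome III, 224399 to 224734) was in G170D alone with 500 bp.

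Ribosome biogenesis promoters kept their hotspots less often than most random lists did, and ribosomal protein promoters about as often. Of 35 genes for ribosome assembly factors, 29 had a WT promoter hotspot and 22 of these kept it, while 0 gained one. The kept share of 75.9% compared with a mean of 87.5% in matched random lists and stood at percentile 2.52, at the edge of the 2.5 limit. It was past that limit with windows of 250 bp (percentile 2.35) and 1000 bp (0.92), and inside it without score matching (3.18) and with equal list lengths (5.67). Promoters with a hotspot in WT alone included those of DIM1, an rRNA dimethylase gene (chromosome XVI, WT hotspot 39102 to 39199), and IMP4, a small-subunit processome gene (chromosome XIV, 485292 to 485500). MAK16 (chromosome I, 101428 to 101650) and NOP2, an rRNA methyltransferase gene (chromosome XIV, 510139 to 510335), belonged to this class as well, and the WT hotspots of all 4 were at most 223 bp wide. Only 19 bp of the DIM1 hotspot lay in the promoter window, and it overlapped a G170D hotspot outside that window. Of 137 cytosolic ribosomal protein genes, 122 were in both strains, 9 in WT alone and 2 in G170D alone, with a kept share of 93.1% against 94.1% in matched random lists (percentile 29.3, or 96.7 without score matching). RPL18B, RPL35B and RPL5 were among those in WT alone. Of 11 RNA polymerase subunit genes 9 were in both, RPA135 in WT alone and RPB8 in G170D alone. Of 17 RSC subunit genes 12 were in both and ARP7, RSC1, RSC2 and RSC3 in WT alone, a kept share of 75% against 78.3% (percentile 35.8).

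Iron uptake promoters gained hotspots in the mutant. Of 13 iron regulon genes, the targets of Aft1 and Aft2, 5 had a promoter hotspot in G170D alone, 38.5% against 3.74% in random lists (percentile 99.995). They were FIT1 (chromosome IV, 1503314 to 1504900), FIT2 (chromosome XV, 1059531 to 1059992) and FIT3 (chromosome XV, 1060441 to 1061055), which encode cell wall mannoproteins that retain iron carriers, with 129, 215 and 333 bp of promoter covered. The others, named after their values were seen, were SIT1, a siderophore transporter gene (143 bp), and HMX1, the heme oxygenase gene (500 bp). ARN2 had an 11 bp hotspot in WT alone. At FIT2 the highest-scoring G170D hotspot overlapped WT hotspots outside the window. Another G170D hotspot in that window (1059328 to 1059468) met no WT hotspot. Among genes without a WT promoter hotspot, 62.5% of the 8 in the list gained one (percentile 99.5). With a 1000 bp window the list's percentile was 96.3, within the limits. FIT2 and FIT3 are neighbours on chromosome XV, and random lists were not matched on position, so the 5 promoters need not be independent. Of 21 ergosterol genes 17 were in both and ERG1, ERG8 and ERG10, enzymes of sterol synthesis, in G170D alone (14.3% against 3.66%, percentile 97.7), but percentiles were 96.7 with a 250 bp and 91.9 with a 1000 bp window.

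Promoters of the other nutrient lists changed class in few genes. All 7 hexose transporter promoters had a hotspot in both strains, but the highest-scoring one touching the promoter was narrower in G170D for each of the 4 named genes. At HXT1 (chromosome VIII, 290913 to 292625) it measured 2462 bp in WT and 101 bp in G170D, at HXT2 (chromosome XIII) 1540 and 142 bp, at HXT3 (chromosome IV, 1162957 to 1164660) 2695 and 59 bp, and at HXT4 (chromosome VIII) 2096 and 758 bp. At HXT2 a single hotspot understates what is left in the 500 bp window, which was covered over 500 bp in WT and 270 bp in G170D. The window was covered over 500 and 101 bp at HXT1, and 413 and 377 bp at HXT4. The wide WT hotspot upstream of HXT3 was broken into 3 in G170D, which left 9 bp of its promoter window covered. Of the others, named after their values were seen, HXT5 (500 and 500 bp) and HXT6 (459 and 455 bp) hardly changed and HXT7 had 500 and 372 bp. Of 9 glucose-repressed genes 8 were in both and ADH2, the ethanol-oxidising dehydrogenase gene, in G170D alone. Of 19 respiration genes 17 were in both and SDH2 in G170D alone, and of 18 glycolytic genes 16 were in both and HXK2 in WT alone. Among 7 galactose genes 6 were in both. For 11 phosphate starvation genes the count was 8, with PHO5, the secreted acid phosphatase gene, in WT alone. Of 18 Gcn4 targets in amino acid synthesis 12 were in both, ARO4 in WT alone and HIS3 and TRP5 in G170D alone. None of these lists stood in the outer 2.5% of random lists on either side.

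The remaining lists also stood within those limits. As matched here, those lists and the other nutrient lists that kept every promoter or gained none were at their bound. They could not have passed the limit on that side. All 10 histone promoters had a hotspot in both strains, as did 5 of 6 a-specific and 3 of 4 alpha-specific genes, the mating-type sets. FUS1 and FUS2, cell fusion genes, were in WT alone among 12 pheromone response genes, of which 10 were in both. Of 31 proteasome genes 23 were in both, PRE8, RPN2 and RPN6 in WT alone and PUP2 and RPN1 in G170D alone, RPN6 being named after its values were seen. Of 18 G1/S genes 15 were in both and RNR1, the ribonucleotide reductase gene, in WT alone. The RNR1 hotspot was 24 bp wide, with a score of 3.57 near the lowest of the WT list. Among 36 genes named PAU or COS, 28 had no promoter hotspot in either strain, 3 had one in both, COS111 and PAU2 in WT alone and PAU5, PAU7 and PAU20 in G170D alone, PAU7 being named after its values were seen. Their gained share stood at percentile 90.8 among all genes, at 98.25 with a 1000 bp window and at 6.69 among genes without a WT promoter hotspot. COS111 shares the name, but at 2775 bp it is longer than the other COS genes listed (COS9, the next longest, has 1224 bp) and may not belong with them. The other members belong to families of near-identical sequence, so their hotspots are uncertain.

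**Figure D3:**
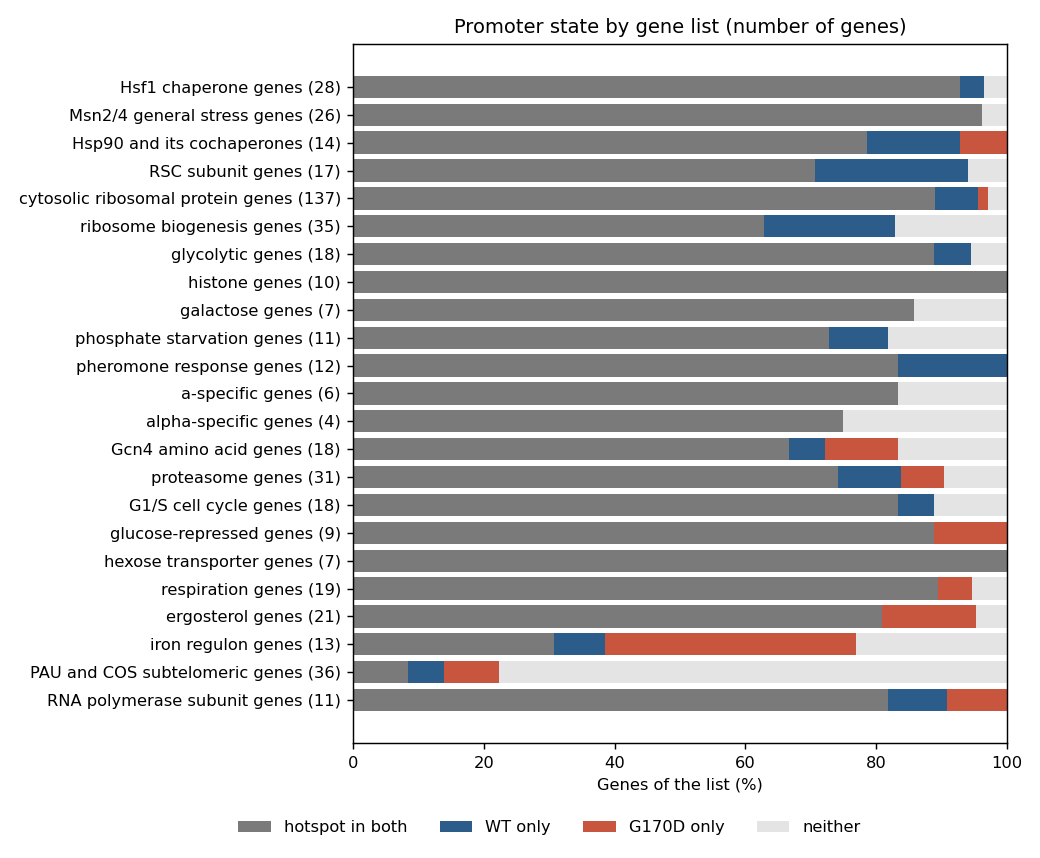
Share of the genes of each list (x axis, percent) whose promoter held a hotspot in both strains (grey), in WT alone (blue), in G170D alone (red) or in neither (light grey), 1 library per strain, with the number of genes in brackets. The iron regulon has the longest red part, 5 of 13 genes, and the ribosome biogenesis list has 7 of 35 genes in blue.

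**Figure D4:**
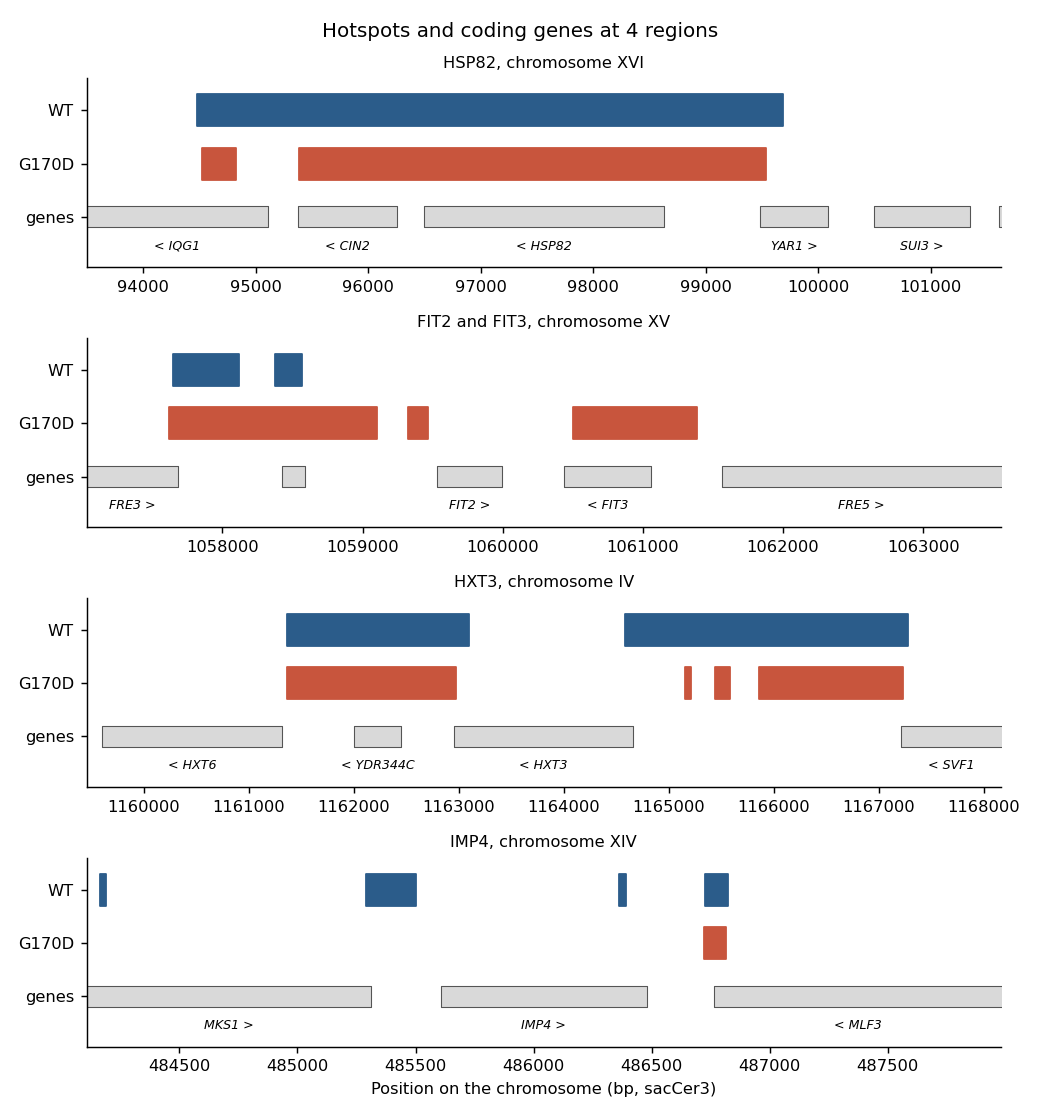
Hotspots of WT (blue) and G170D (red) and annotated coding genes (grey, arrow marks give the strand) along 4 regions (x axis, position in bp, sacCer3). HSP82 is covered in both strains, FIT3 has a hotspot in G170D alone (1060504 to 1061388), the 2695 bp WT hotspot upstream of HXT3 is broken up in G170D, and IMP4 has its promoter hotspot in WT alone.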

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

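Merging at 300 bp, the 100 bp width minimum, the overlap anywhere in the genome, the WT-closed background, the equal-length lists for gene lists and the matching on WT body coverage were chosen after seeing the data; the other alternatives were planned. Under them 216 values stayed within their interval, within 1.5 times (counts) or on their side of the limit, 25 moved, and list percentiles crossed the limit outward 4 times and inward 5 times. Percentiles inside the limits were loose: the gained percentile of PAU and COS genes went from 90.8 to 6.69 and that of ribosomal protein genes from 7.86 to 77.2 among genes without a WT hotspot. The share of WT hotspots also found in G170D was 74.98% in the upper 50% of scores, 80.5% with equal list lengths, 76.2% with 300 bp merging, 75.2% at 100 bp or more and 49.3% when 50% of both hotspots had to overlap. The G170D share was 89.2%, 85.8%, 92.1%, 92.1% and 58.1% under these same settings, 89.4% with 50% of the shorter hotspot and 91.0% within 150 bp. Random placement upstream of coding starts gave 41.2% for WT, and 76.0% for G170D, closer to the observed 90.2%. It put every G170D midpoint upstream of a coding start, where only 38.8% of the real ones lay. Neither value is thus a matched background. Unlike in the main placement, hotspots placed this way could overlap each other and so covered fewer bases. The 41.2% is therefore not comparable with the 47.4% of the main placement. The narrower share was 70.2% in the upper 50% of scores, and the median width change was -63 bp with 300 bp merging and -41 bp with 50% of both. Promoters in both, in WT alone and in G170D alone numbered 3074, 690 and 371 in the upper 50% of scores, and 4242, 440 and 321 with equal list lengths. Those in G170D alone whose highest-scoring hotspot had no overlap anywhere were 142. By midpoint, 2184 were in both, 997 in WT alone and 677 in G170D alone. Upstream shares with 250 and 1000 bp windows were 23.3% and 53.1% in WT and 25.2% and 56.4% in G170D, since the window itself sets them. Percentiles of kept promoters were 2.35 (250 bp) and 0.92 (1000 bp) for ribosome biogenesis, and 97.85 without score matching for Msn2/4 genes. Percentiles of gained promoters were 96.66 (250 bp) and 91.91 (1000 bp) for ergosterol, 96.34 (1000 bp) for iron and 98.25 (1000 bp) for PAU and COS genes. Matching on WT body coverage gave percentiles of 93.6 for iron genes and 95.6 for the 57 glutamine- and asparagine-rich ones. Apart from the window shares, the cause was not tested. Merging at 150 bp changed nothing, because no neighbours lay that close, and the motif alternatives were not run. Unknown depth limits every count.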

Other observations

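Promoter and coding-body coverage by list, and the test of chromosome ends, were chosen after results were seen, as were the genes named in this part. More lists stood in the outer 2.5% on either side by how much of the promoter window was covered than by presence of a hotspot. The measures were matched differently, coverage on WT coverage, the kept share on WT score and the gained share on neither, so they were not compared directly. Mean coverage over all 6002 genes was 293 of 500 bp in WT and 268 bp in G170D. Ribosome biogenesis promoters went from 287 to 193 bp (percentile 0.06 of 10000 random lists matched on WT coverage), with 23 of 35 less covered and 4 more. NIP7 (500 and 126 bp), NOP7 (500 and 221 bp) and NOP56 (500 and 216 bp) kept a hotspot but lost most of the window. Hexose transporter promoters went from 482 to 298 bp (percentile 1.23), 6 of 7 being less covered, with 500 and 9 bp at HXT3. HXT1, HXT4 and HXT5 lie close together on chromosome VIII, and HXT3, HXT6 and HXT7 on chromosome IV, so these promoters need not be independent. Proteasome promoters went from 305 to 226 bp (percentile 1.21), 20 of 31 being less covered. Msn2/4 promoters went from 403 to 443 bp (percentile 99.99), with RTN2 at 41 and 472 bp and TFS1 at 153 and 500 bp, although 16 of 26 were equal. Iron regulon promoters went from 108 to 238 bp (percentile 99.6), FET3, a ferroxidase gene with a hotspot in both strains, having 123 and 500 bp. Phosphate starvation (percentile 99.1, 3 of 11 more covered and 2 less) and glucose-repressed promoters (99.3, 5 of 9 more and 2 less) also lay in the outer 2.5% on the high side. So did ergosterol promoters (98.0), although 8 were less covered and 6 more and ERG1 alone added 500 bp. Cytosolic ribosomal protein promoters stood highest of the 23 lists (percentile 100), since they lost only 8.12 bp on average against 46.1 bp in matched lists, with 42 less covered and 31 more. Those random lists were not matched on score, and with score matched the kept share of this list stood at percentile 29.3. Of the 23 lists 3 stood in the low and 6 in the high 2.5%, and a window already full in WT cannot gain.

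Coding bodies were covered to 29.5% on average in WT and 26.0% in G170D, with 9.43% of genes gaining more than 20 points and 15.3% losing as much. Beyond 50 points, 241 genes gained and 166 lost. Msn2/4 genes gained 9.35 points on average (percentile 99.6 among length-matched lists, 99.7 when matched on WT coverage too), but 12 gained and 11 lost, with a median of 0. The mean rests on 5 genes that gained over 20 points: DDR2, a stress-induced gene (chromosome XV, 231570 to 231755), went from 0% to 100%, and SOD2, the mitochondrial superoxide dismutase gene (chromosome VIII, 122889 to 123590), from 20.8% to 97.6%, while NTH1, a trehalase gene, lost 25.7 points. The SOD2 promoter window held no hotspot in either strain. The G170D hotspot over its body (121527 to 123573) was the one upstream of the neighbouring ergosterol gene ERG11. Iron regulon genes started at 9.98% in WT and gained 11.6 points (percentile 98.5), which was within the limits when lists were matched on WT coverage too (93.6). Of the 13, 6 gained, 2 lost and 5 did not move, with FIT3 going from 0% to 89.8% and FRE1, a ferric reductase gene, from 56.2% to 17.2%. The coding bodies of LEU2, TRP1 and HSP82 were covered in full in both strains, and the labels do not say whether either strain carries extra copies of them. The highest score of both lists lay at the rDNA over RDN5-1 (chromosome XII, 459700 to 460653), with the same coordinates in each, and reads from such repeats cannot be placed uniquely.

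WT had more hotspots than G170D and wider shared ones. Hotspots found in 1 strain were mostly weak in their own list: 6.29% of the 1876 WT-only and 18.5% of the 585 G170D-only ones lay in the upper 50% of scores. With depth unknown and 1 library per strain, neither a technical nor a biological explanation was tested. Among the 3992 hotspots shared one to one, changes over 500 bp were near even, with 131 wider in G170D and 139 narrower. Hotspots broken into several in the other strain, as at HXT3, were not counted there. The lists above moved both ways.

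Some strong hotspots were called in G170D alone, 46 of them in the top 20% of G170D scores, against 0 WT-only hotspots in the top 20% of WT scores. Whether the calling threshold differed between the lists was not tested. Repeated sequence at chromosome ends covers a part only: 8 of the 46 lay within 20 kb of an end (17.4%, Wilson 9.09 to 30.7). Ends were still over-represented, since only 123 of all 5988 G170D hotspots lay within 20 kb of one. The farthest of the 8 was 0.502 kb from its end. Of the 46, 28 lay in coding bodies (60.9%, against 67.5% of all G170D-only hotspots), such as those of GAL11 (chromosome XV, 235914 to 236772), SNF2 (chromosome XV, 855326 to 856218) and HAP1 (chromosome XII, 646859 to 647761). Coding sequence rich in glutamine and asparagine codons was left open: a list of 64 such genes, compiled from general knowledge after 7 had been noticed, stood at percentile 99.99 for mean gain of body coverage among length-matched lists, and the 57 not noticed before at 98.98. These 57 were covered to 15.8% in WT, against 29.5% over all genes, and so had less to lose: with random lists matched on WT coverage too, their percentile was 95.6, within the limits (99.85 for all 64), with 21 gaining, 32 losing, and 7 gaining and 3 losing over 20 points.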
